A study of Bacillus subtilis subsp. subtilis str. 168 with 8 samples.

How the data were processed

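The deposited data were 8 Agilent 2-colour array files and a series matrix. Per the labels, RNA came from strains WN624 and WN1106 grown in LB for 24 h at 5 or 101 kPa, total RNA was labelled with Cy5 and Cy3, and each array paired a Cy5 with a Cy3 sample. Per the file headers, the scanned images were read with Feature Extraction 10.1.1.1, and the deposited mean signals, median local backgrounds and processed signals are in units of intensity, the processed signals background-subtracted, detrended and dye-normalized within each array. The deposited log ratios of the array files are on the log10 scale. The series matrix values, deposited by the authors, were found from the values to be log10 of Cy5 over Cy3 per gene: each column correlated with its own array at 0.938 to 0.998, with slopes of 0.971 to 1.21, and had a median of -0.0157 to 0.00125. The submitters' processing notes name limma for them and give neither version nor settings, so their background correction and normalization are unknown.

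Each array held 15208 gene spots, with 8214 probes for 4102 genes, and 536 control spots. Of the genes 40 had 1 probe, 4012 had 2 and 50 had 3. Gene symbols were taken from the RefSeq table of assembly ASM904v1 by locus tag, which matched 4034 genes, and 68 had no match and no symbol. The table lists des as desE, hmp as hmpA and ldh as lctE, and older symbols in the gene lists were matched through aliases. The symbol epsK stands at 2 loci in the table, and the one on the array, BSU04280, lies outside the eps operon, so the biofilm list holds a gene of another locus. All 8 arrays were on 1 slide with 1 scan time. On the pressure arrays the labels tag both pressures under the same channel, so the orientation was taken from the titles, which put the lower pressure first. It was checked by closing the loop of the comparison arrays: the spread of the closure over all genes was an SD of 0.106 as labelled and 0.836 with both pressure arrays turned.

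The ratios were computed from the array files with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8, and statmod 1.5.0). Mean signals were corrected for median local background by normexp with an offset of 50, the log2 ratios of Cy5 over Cy3 were normalized by loess within each array, and spots were averaged per probe and probes per gene. The offset holds back the ratios of dim genes. Spots marked as outliers by Feature Extraction, 20 to 43 per array, were left out, and no gene spot was saturated. A gene was tested if it was well above background in at least 1 channel of at least 1 array, which held for 4073 genes and set 29 aside. Genes that were dim in all channels of a condition numbered 135 for WN624 at 101 kPa, 37 for WN624 at 5 kPa, 95 for WN1106 at 101 kPa and 72 for WN1106 at 5 kPa, and for these a change is compressed by the background.

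All 8 arrays entered 1 limma fit (lmFit and eBayes) with a dye term per gene, which the 4 same-against-same arrays estimate, and 3 parameters for the 4 conditions, leaving 4 residual degrees of freedom. The spread thus comes from the same-against-same arrays and from the closure of the loop. The median standard error was 0.0756, and 0.0654 for the averages. From this fit came the pressure change in each strain, the strain difference at each pressure, the interaction and the averages over strains and over pressures. P-values were adjusted by Benjamini and Hochberg over the 4073 genes of a comparison, with a threshold of 0.05, and again over each list alone. As the same conditions enter neighbouring comparisons, unrelated errors alone gave correlations near 0.50 in simulated data but a covariance of 0.0037, against 1.53 for the pressure changes of both strains and 0.0452 for the strain differences at both pressures.

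The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, in each of the 4 comparisons, the 12 highest and the 12 lowest genes past the threshold that were above background on the direct array and had the same sign there, 16 genes chosen in advance whatever their values, and 2 to 4 members with the largest changes of each list that was called. For the interaction and the averages it named the 5 highest and the 5 lowest. The 29 gene lists cover general stress (SigB), the membrane desaturase and its sensor system, fatty acid synthesis, cold shock, flagella and chemotaxis, oxygen limitation, terminal oxidases and the bc complex, ATP synthase, the TCA cycle, glycolysis, heat shock, peroxide and disulfide stress, iron uptake (Fur), envelope stress (SigW), early and late sporulation, competence, biofilm matrix, antibiotic synthesis, extracellular proteases, ribosomal proteins, purine, pyrimidine, arginine and branched-chain amino acid synthesis, compatible solutes, the SOS response (LexA), the PBSX prophage and acetoin use. Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation. With the estimated correlation camera also rests on the 4 residual degrees of freedom, which leaves it little power at any correlation. The lists were tested as well with fry, which asks only whether the list's own genes move. The p-values were adjusted over the lists of a comparison. Some list members matched no gene on the array and were left out. Of the 99 written for SigB 83 matched, of 33 for Fur 24 and of 49 for SigW 45, and other lists lost fewer.

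The procedure was tested on simulated data. Of 50 genes changed by 0.25 on the log2 scale 17 were recovered. Of 50 changed by 0.5, by 1 and by 2 the test recovered 40, 49 and 50, and 8 of 3843 unchanged genes were called. A list of 30 genes shifted by 0.3 was called (camera adjusted p = 1.61e-23). Most simulated genes were unchanged, whereas 3057 genes passed for pressure in WN624. The power of the list test in the real comparisons is therefore not known from this simulation.

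The alternatives tried were Agilent's processed signals, no background correction, median centring of each array only, scale normalization between arrays, no filter, a filter for genes above background in all 16 channels (3555 genes), the median of the probes, no dye term, eBayes with trend and robust settings, the series matrix values, a fit of the separate channels with the spot as a block (correlation within spots 0.595, 11 residual degrees of freedom), the direct arrays only, each array left out in turn, fry and the estimated correlation in place of the preset one, and the SigB list without genes that other regulators also control. A fit with the slide as a block was not run, as all arrays lay on 1 slide.

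Added after seeing the data were a test for changes of more than 2-fold (limma treat), counts of genes changed at least 2-fold, the biofilm list without the gene matched as epsK, and the subtraction of a share of each spot's Cy3 signal from its Cy5 signal before normexp. The share, 1.82%, came from genes with a Cy3 signal of at least 1000 units on a pressure array. After division by the array's median ratio of Cy3 to Cy5, that signal had to be at least 12 times the Cy5 signal implied by the same-against-same array of the condition, from which the excess was taken. In data simulated with a share of 2% the procedure returned 2.04%, and -0.0929% where none was added. Control spots were used for no comparison.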

Results

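Gene expression was measured with Agilent 2-colour arrays in total RNA of Bacillus subtilis strains WN624 and WN1106, grown in LB medium for 24 h at 5 kPa or at 101 kPa, which is ordinary air pressure. The strains and pressures made 4 RNA conditions, and 8 arrays were deposited. On 4 comparison arrays a condition was set against another: the pressures in WN624, the pressures in WN1106, the strains at 101 kPa and the strains at 5 kPa. On the other 4 arrays both channels carried the same condition. The median net signal of the gene spots was 260.1 to 559 in Cy5 and 134 to 276 in Cy3, and 3757 to 4027 of 4102 genes were well above background in a channel. No gene spot was saturated. The number of arrays limits the precision: each comparison had 1 direct array and no dye swap, so all 8 arrays were fitted together with limma.

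The labels do not name separate cultures, so each value rests on RNA whose number of cultures is unknown. The standard errors and p-values below measure the spread between arrays and labelled RNA, not the spread between cultures, and no check with replicate cultures was possible. All changes are log2 values with the standard error of the fit, and 4073 genes were tested. Changes are relative to the typical gene of an array, because each array was centred.

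The first comparison asks how WN624 responded to growth at 5 kPa. The largest rise was that of sboA (BSU37350), which encodes the precursor of the bacteriocin subtilosin, at 7.90 ± 0.20, or 239.6-fold (limma adjusted p = 9.09e-11). Its neighbours for subtilosin maturation and immunity rose with it, albE by 7.23 ± 0.09, albF by 7.04, albG by 6.85, albA by 6.63 and albB by 6.42, as did sboX of the same operon by 7.11. Genes of the general stress regulon also rose: mgsR, a regulator of part of that regulon, by 6.78 ± 0.11, gsiB by 6.70 ± 0.13, yfhK by 6.80, gspA by 6.33 and sigB, the stress sigma factor itself, by 6.09 ± 0.08. The largest fall was that of dctP (BSU04470), the transporter of C4-dicarboxylates, at -5.59 ± 0.24 (adjusted p = 4.89e-09). It was followed by other genes for the uptake of carbon sources.

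Among those falls, treP for trehalose uptake stood at -5.38 ± 0.11, pftA and pftB for pyruvate uptake at -4.88 and -4.38, iolT for inositol at -4.77, mleN for malate and lactate at -4.67, citM for citrate at -4.51 and glpF for glycerol at -4.41. The regulator msmR lay at -4.48 and sxzZ at -4.37. The ferric hydroxamate permease gene fhuB fell by 4.36 and the flavodoxin gene fldN fell by 4.32. The genes yjdB and ybyB rose by 6.75 and 6.57. Among the genes fixed in advance, narG of nitrate reductase rose by 5.23 ± 0.09, cydA of cytochrome bd oxidase by 4.83, lctE for lactate dehydrogenase by 3.31, the catalase gene katE by 5.07, ctc by 3.10, the response regulator gene resD by 2.70, the spore protein gene sspB by 2.62 and the fatty acid desaturase gene desE by 2.23 ± 0.07. The sensor gene desK rose by 1.09 and its regulator desR by 0.72. The cold shock gene cspB fell by 1.22, the flagellin gene hag fell by 0.69 and the surfactin synthetase gene srfAA fell by 0.31, while the flavohaemoglobin gene hmpA, at 0.02 ± 0.07, did not pass (adjusted p = 0.849).

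Of the 29 gene lists, 11 were called in WN624 by camera, and 0 with an estimated correlation. The SigB general stress list stood highest: 77 of its 83 measured genes rose and 1 fell, with a median of 3.26 (camera adjusted p = 1.17e-21, adjusted p = 0.179 with an estimated correlation). In the list of genes for oxygen limitation, 21 of 28 rose, among them narI, narH and narJ at 5.72, 5.71 and 5.38, and 4 fell. Their median was 2.24 (camera adjusted p = 2.75e-05, adjusted p = 0.179 with an estimated correlation). In the list of terminal oxidases and the bc complex 17 of 20 rose and 2 fell (median 2.02, camera adjusted p = 2.25e-05, adjusted p = 0.179 with an estimated correlation). Among its members were cydC at 5.85, cydB at 5.46 and cydD at 3.82, which serve cytochrome bd oxidase, cydC and cydD in its assembly. Antibiotic synthesis genes rose in 39 of 51 cases and fell in 5, led by the subtilosin genes (median 1.07, camera adjusted p = 2.03e-07, adjusted p = 0.182 with an estimated correlation).

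Flagella and chemotaxis genes rose in 48 of 56 cases and fell in 1, with fliG at 3.20, fliH at 3.12, fliF at 2.87 and fliI at 2.82. Over the list the median was 0.98 (camera adjusted p = 9.84e-09, adjusted p = 0.179 with an estimated correlation). The 1 member that fell was hag, the filament protein. Iron uptake genes under Fur fell in 23 of 24 cases and rose in 1, with the flavodoxin genes fldN and fldP at -4.32 and -4.27 and ykuO at -4.27. The list had a median of -3.14 (camera adjusted p = 9.84e-09, adjusted p = 0.179 with an estimated correlation). Biofilm matrix genes fell in 18 of 19 cases and rose in 1, with epsA at -3.04, epsB at -2.53 and epsF at -2.42 of the exopolysaccharide operon. The gene that rose, matched by its symbol epsK, is a locus outside that operon, and without it all 18 fell (camera adjusted p = 1.52e-07). The median over the list was -1.83 (camera adjusted p = 8.49e-07, adjusted p = 0.182 with an estimated correlation). In the fatty acid synthesis list 12 of 15 rose and 3 fell, with the regulator gene fapR at 2.75, plsX at 1.92 and accC at 1.58 against fabZ at -2.03. The median of the list was 0.87 (camera adjusted p = 0.0358, adjusted p = 0.372 with an estimated correlation).

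Peroxide and disulfide stress genes rose in 16 of 20 cases and fell in 2, with the iron efflux gene pfeT at 2.97, spxA at 1.86 and mrgA at 1.33 against tpx at -2.10. Their median was 0.68 (camera adjusted p = 0.00684, adjusted p = 0.179 with an estimated correlation). Glycolysis genes fell in 9 of 13 cases and rose in 2, with ptsG for glucose uptake at -3.66, gapA at -2.55 and pgi at -1.52. The list also holds ptsH and ptsI for sugar uptake, both at -1.37, and the regulator gene cggR, at -0.99. The enzyme genes tpiA, pgk, pgm and eno stood at 0.31, 0.22, 0.44 and -0.09, so the fall did not run through the pathway. Over the list the median was -0.75 (camera adjusted p = 0.0288, adjusted p = 0.432 with an estimated correlation). In the TCA cycle list 12 of 17 fell and 3 rose, with sdhC, sdhB and sdhA of succinate dehydrogenase at -1.70, -1.41 and -1.32. The list had a median of -0.64 (camera adjusted p = 0.0358, adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone, these 11 lists gave the counts above except glycolysis, with 3 genes up and 9 down.

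Of the lists not called in WN624, 7 of 8 extracellular protease genes rose (median 0.35, camera adjusted p = 0.0768) and so did all 3 genes of the membrane desaturase list (median 1.09, camera adjusted p = 0.0768). In acetoin and overflow use 6 of 9 rose and 3 fell, in arginine synthesis 4 of 9 rose, and in competence 12 of 25 rose and 6 fell. In compatible solutes 7 of 18 rose and 9 fell, 7 and 10 adjusted over the list alone. In late sporulation 19 of 60 rose and 8 fell, 18 and 7 adjusted over the list alone. In SigW envelope stress 15 of 45 rose and 23 fell, in the LexA SOS response 4 of 15 rose and 5 fell, and 2 of the 3 cold shock genes fell. These lists had camera adjusted p-values of 0.69 for acetoin, 0.367 for arginine synthesis and for competence, 0.947 for compatible solutes, 0.651 for late sporulation, 0.13 for SigW, 0.958 for LexA and 0.249 for cold shock. Mean and median differed in sign for branched-chain amino acid synthesis (0.09 and -0.23), compatible solutes (0.67 and -0.23) and heat shock (0.37 and -0.16), and the test ran down for all of them, as it did for LexA (median 0.02) and pyrimidine synthesis (median 0.02).

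In all, 3057 genes passed in WN624, 1582 up and 1475 down, and 1177 of these changed at least 2-fold, 656 up and 521 down. Of the 2-fold changes 55.7% were up, against 46.9% with median centring alone, 45.7% in the deposited series matrix values and 74.9% after scale normalization between arrays, which left 1082 genes passed and 215 changed at least 2-fold and ended the calls of desK, desR, cspB, srfAA, spxA, mrgA and sdhC. With 1.82% of each spot's Cy3 signal taken off its Cy5 signal, dctP stood at -7.17, treP at -6.67, pftA at -5.85, iolT at -5.84, mleN at -5.85, citM at -5.25, glpF at -5.16, sxzZ at -5.06, pftB at -4.97 and fhuB at -4.98. Named genes were counted as moved where their ratio, not their log2 value, shifted by more than 1.5-fold. With Agilent's processed signals, which carry no offset, 29 of the 72 named genes lay this much farther from 0. Among them were narI at 7.75, epsA at -5.11 and cydA at 6.97. After scale normalization 69 of the 72 lay nearer 0 by more than 1.5-fold. Without the WN624 pressure array dctP stood at -6.64 and srfAA, at -0.06, was no longer called, nor were fatty acid synthesis (adjusted p = 0.0577), glycolysis (0.0577) and the TCA cycle (0.187). The call of peroxide and disulfide stress ended with median centring (adjusted p = 0.239) and scale normalization (0.394), that of fatty acid synthesis with median centring (0.282) and in the series matrix values (0.061), and that of the TCA cycle with the filter for genes above background in all 16 channels (0.0501). The sboA rise was 7.09 in the series matrix values and 8.68 in a fit of the separate channels.

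The same question was asked of WN1106, with 5 kPa again set against 101 kPa. Among the largest rises were those of the nitrate reductase operon: narI (BSU37250) by 8.39 ± 0.11 (limma adjusted p = 1.59e-12), narH by 8.19 ± 0.09, narJ by 7.99 and narG by 7.95. At 101 kPa narI was well above background in 1 of 4 channels and narG in 3 of 4. Their size depends on the processing: Agilent's processed signals gave 9.79 and 9.35. The lactate permease gene lctP rose by 8.04 ± 0.08 and lctE, for lactate dehydrogenase, by 5.46 ± 0.06. The subtilosin precursor gene sboA rose by 7.98 ± 0.20 in this strain too. The inositol catabolism operon held most of the largest falls, with iolE (BSU39720) at -5.09 ± 0.40 (adjusted p = 5.52e-07), iolF at -4.92 ± 0.41, iolI at -4.83 and iolG at -4.82.

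Further along the same operon iolH stood at -4.73, iolD at -4.72, iolC at -4.66 and iolB at -4.50, and the inositol transporter gene iolT fell by 4.60 ± 0.08. The glycerol phosphate transporter gene glpT stood at -4.72 ± 0.16, mleN at -4.62 and sxzY at -4.58. Other strong rises were yjdB by 7.72, yoqM by 7.51, the chitosanase gene csn by 7.23 ± 0.07, yfhK by 6.79, cydC by 6.78 and nhaX by 6.69. Of the genes fixed in advance, desE rose by 4.44 ± 0.07, desK by 4.15, desR by 3.48, sigB by 5.47, cydA by 4.95, gsiB by 4.73, katE by 3.79, ctc by 3.60, resD by 1.3, hag by 1.11 and hmpA by 0.41. Not past the threshold were srfAA at 0.21 ± 0.09 (adjusted p = 0.0502), sspB at 0.17 ± 0.11 (adjusted p = 0.177) and cspB at -0.09 ± 0.13 (adjusted p = 0.537).

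By camera 14 lists were called in WN1106, and 0 with an estimated correlation. General stress genes rose in 82 of 83 cases and none fell, with mgsR at 6.21, gspA at 6.01 and yoxC at 5.57. The median over the list was 3.33 (camera adjusted p = 5.66e-22, adjusted p = 0.149 with an estimated correlation). All 3 desaturase genes rose (median 4.15, camera adjusted p = 0.0148, adjusted p = 0.222 with an estimated correlation). Oxidase and bc complex genes rose in 17 of 20 cases and fell in 1, with cydB at 5.64, cydD at 5.06 and ctaD, ctaE and ctaC at 4.46, 4.41 and 4.21. The median of the list was 3.18 (camera adjusted p = 6.94e-06, adjusted p = 0.137 with an estimated correlation). The ctaD, ctaE and ctaC products belong to cytochrome c oxidase. Oxygen limitation genes rose in 21 of 28 cases and fell in 4 (median 1.61, camera adjusted p = 0.000194, adjusted p = 0.137 with an estimated correlation).

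Antibiotic synthesis genes rose in 45 of 51 cases and fell in 4, with sboX at 6.63, albE at 6.35 and albB at 6.09. Their median was 1.64 (camera adjusted p = 8.95e-10, adjusted p = 0.149 with an estimated correlation). Peroxide and disulfide stress genes rose in 17 of 20 cases and fell in 1, with pfeT at 3.99, spxA at 2.74, mrgA at 2.72 and the thioredoxin reductase gene trxB at 2.52. Over the list the median was 1.54 (camera adjusted p = 0.000112, adjusted p = 0.137 with an estimated correlation). Early sporulation genes rose in 15 of 33 cases and fell in 2, with spoIIAB at 2.42, spoIID at 2.40 and sigF at 2.26. The list had a median of 0.18 (camera adjusted p = 0.0369, adjusted p = 0.222 with an estimated correlation). Of the ATP synthase genes 8 of 9 rose, with atpA at 0.79 and atpF at 0.72 (median 0.59, camera adjusted p = 0.0297, adjusted p = 0.551 with an estimated correlation), but with median centring alone atpA stood at -0.60, atpF at -0.59, atpH at -0.63 and atpC at -0.70, and the list's median at -0.70.

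Iron uptake genes fell in 23 of 24 cases and rose in 1, with dhbC, dhbE and dhbB of bacillibactin synthesis at -4.32, -4.03 and -4.01 and the siderophore binding protein gene feuA at -3.90. The median over the list was -3.34 (camera adjusted p = 3.04e-09, adjusted p = 0.149 with an estimated correlation). Biofilm matrix genes fell in 17 of 19 cases and rose in 2, with epsA at -2.45 and the hydrophobin gene bslA, which rose, at 2.66. The other that rose was the epsK locus outside the operon, without which the call stayed (camera adjusted p = 9.12e-06). The median of the list was -1.81 (camera adjusted p = 3.1e-05, adjusted p = 0.222 with an estimated correlation). Ribosomal protein genes fell in 41 of 49 cases and rose in 2, with rpsR at -1.37 and rpsF at -1.18. Their median was -0.41 (camera adjusted p = 3.3e-05, adjusted p = 0.441 with an estimated correlation). PBSX prophage genes fell in 26 of 32 cases and rose in 2, with xkdM at -1.13 and xkdH at -1.06 against xkdA at 1.16. Over the list the median was -0.51 (camera adjusted p = 0.000146, adjusted p = 0.149 with an estimated correlation).

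TCA cycle genes fell in 14 of 17 cases and rose in 1, with the aconitase gene citB at -3.52, sdhC at -1.94, citZ at -1.92 and odhA at -1.69. The list had a median of -1.32 (camera adjusted p = 0.000194, adjusted p = 0.445 with an estimated correlation). Glycolysis genes fell in 12 of 13 cases and rose in 1, with gapA at -3.61, ptsG at -3.58 and cggR at -1.37. The median over the list was -1.09 (camera adjusted p = 0.000208, adjusted p = 0.222 with an estimated correlation). Adjusted over the list alone, the 14 called lists gave these counts except antibiotic synthesis, with 46 up and 4 down. For fatty acid synthesis the mean was 0.06 and the median -0.23, and the test, which ran down, did not call the list.

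In WN1106, 3171 genes passed, 1638 up and 1533 down, and 1317 changed at least 2-fold, 754 up and 563 down. Of the 2-fold changes 57.3% were up, against 46.3% with median centring alone, 48.2% in the series matrix values and 74.6% after scale normalization, which left 1121 genes passed and 279 changed at least 2-fold and ended the calls of hag, hmpA, resD, atpA, atpF, atpH, rplJ and rplI and of the ATP synthase (adjusted p = 0.155) and early sporulation lists (0.113). Median centring alone, which moved genes by a median of -0.177, put hag at 0.03, srfAA at -0.58 and cspB, which then passed, at -1.61. It moved 36 of the 83 named genes by more than 1.5-fold. Of these 25 lay farther from 0, such as rpsF at -2.54 and rplJ at -2.32, and 11 nearer. It also ended the calls of PBSX (adjusted p = 0.182) and of peroxide and disulfide stress (adjusted p = 0.0544). The series matrix values, in which genes lay lower by a median of 0.15 and 44.3% of those passed were up, ended the call of ATP synthase (adjusted p = 0.15). The cspB value also passed there, at -0.49, and in the separate-channel fit, at -0.32. Without background correction early sporulation was not called (adjusted p = 0.0709). With Agilent's processed signals 28 of the 83 named genes lay farther from 0 by more than 1.5-fold. Among them were cydC at 8.74, hmpA at 1.52 and sspB at 1.32, which then passed. After scale normalization 74 lay as much nearer 0.

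Among the named genes of this comparison, those of the inositol operon were the ones on which the arrays differed most. Without the WN1106 pressure array iolE stood at -6.89, iolF at -6.78, iolC at -6.66, iolG at -6.60, iolD at -6.59, iolH at -6.28, iolI at -6.18, iolB at -6.10 and feuA at -4.51. Without any 1 of the other 3 comparison arrays the estimate rested on the pressure array alone, with iolE at -4.50, iolF at -4.31, iolG at -4.23, iolD at -4.10 and iolC at -3.99. With the Cy3 share taken off, iolE stood at -6.22, iolF at -5.93, iolI at -5.76, iolG at -5.66, iolH at -5.65, iolD at -5.45, iolC at -5.39, iolB at -5.26, iolT at -5.70, mleN at -5.96, glpT at -5.63, sxzY at -5.30 and dhbC at -5.06. Leaving out the WN1106 pressure array also turned srfAA to -0.05 and raised sspB to 0.54, which then passed.

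Across the 4073 genes the pressure changes of both strains had a correlation of 0.816, a value across genes, which are not independent replicates. At least 2-fold in both strains, 464 genes were up and 320 down, against 121 and 72 for unrelated lists of these sizes, and 8 moved in opposite directions. On average of the strains sboA rose by 7.94 ± 0.17, yjdB by 7.23, narI by 7.05, narH by 6.95 and sboX by 6.87, and iolT stood at -4.69, mleN at -4.64, dctP at -4.60 ± 0.21, pftA at -4.55 and treP at -4.44. For this average 3191 genes passed, 1656 up and 1535 down, and 1103 changed at least 2-fold, 647 up and 456 down. The share of these that was up was 58.7%, against 46.4% with median centring, 48.2% in the series matrix values and 73.0% after scale normalization, which left 1095 and 215 genes. All 10 genes named for the average lay nearer 0 by more than 1.5-fold after scale normalization. Agilent's processed signals put narI at 8.77, sboX at 8.65, narH at 8.41 and treP at -5.07. With the Cy3 share taken off, dctP stood lowest at -5.92, mleN at -5.90, iolT at -5.77, pftA at -5.50 and treP at -5.45. Median centring put yjdB at 6.59, dctP at -5.23 and mleN at -5.25, the separate-channel fit put sboA at 8.68, dctP at -5.36, iolT at -5.33 and mleN at -5.28, and the series matrix values put sboA at 7.29. The average dctP value was -5.30 without the WN624 pressure array and -3.90 without the WN1106 pressure array.

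**Figure D1:**
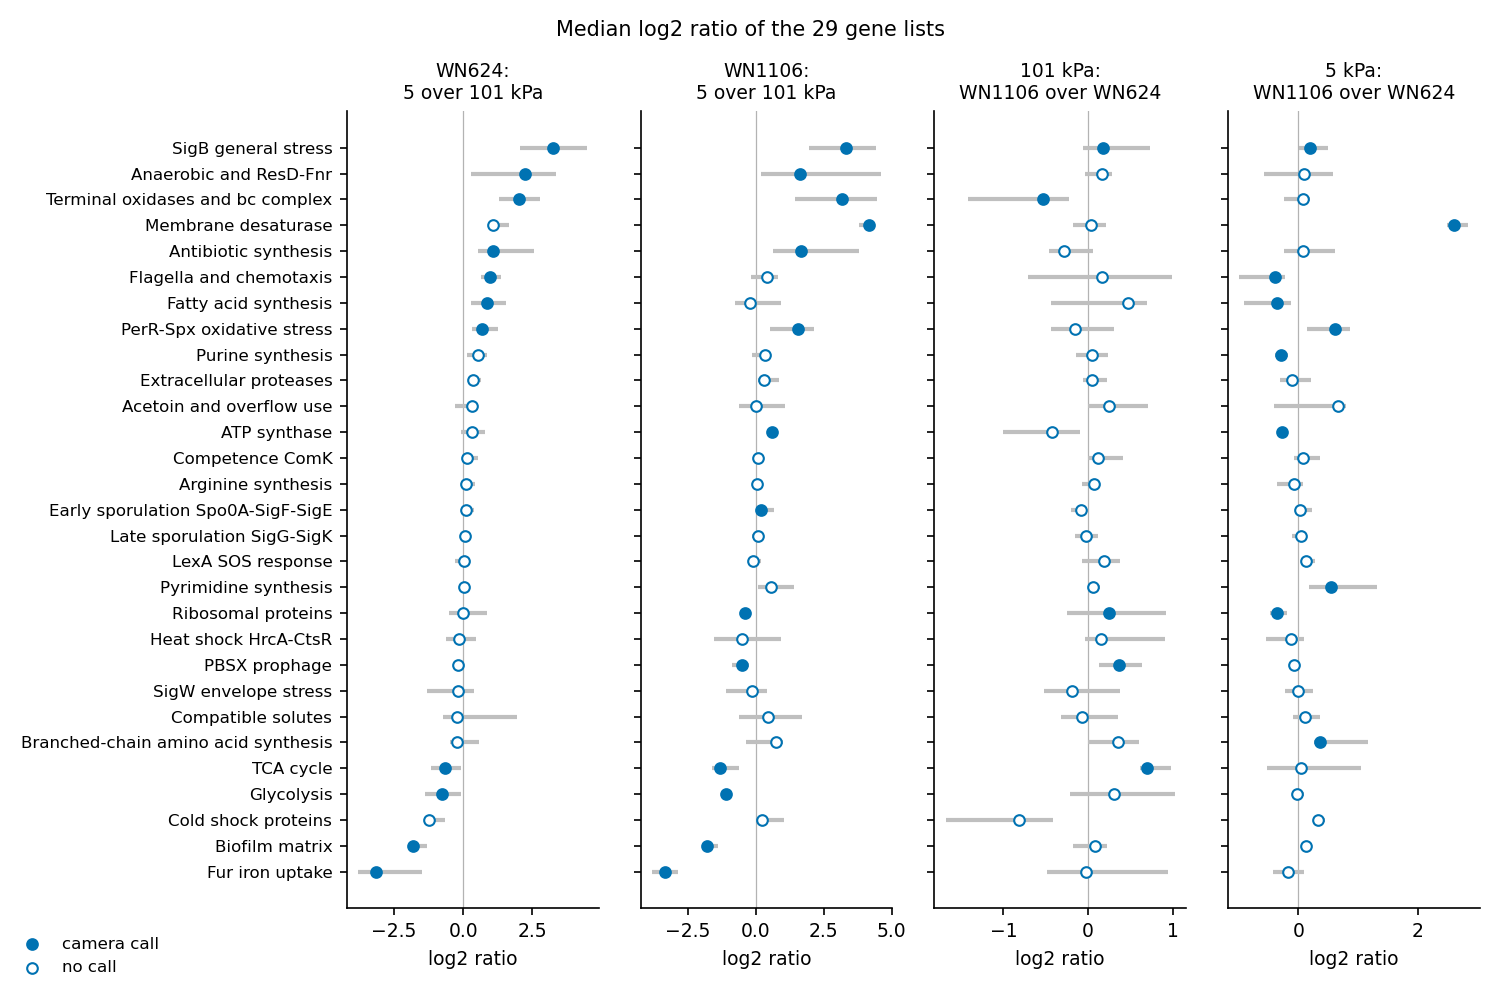
For each gene list, the marker is the median log2 change and the bar spans the quartiles over its measured genes, by comparison, with filled markers for lists called by camera. The SigB list had medians of 3.26 and 3.33 in the pressure comparisons, and the ATP synthase median in WN1106, 0.59, turned to -0.70 with median centring alone.

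The third comparison asks how the strains differed at 101 kPa, WN1106 against WN624. The flagellin gene hag (BSU35360) was lower in WN1106 by the most, at -4.50 ± 0.13 (limma adjusted p = 1.67e-08), followed by ylqB at -4.17 ± 0.07. Both pyruvate uptake genes were lower, pftA at -3.35 and pftB at -2.87, as were yjfB at -3.26, yxjJ at -2.59, the cold shock gene cspD at -2.53, msmR at -2.39, yetK at -2.31, the alpha-galactosidase gene melA at -2.13, yrzI at -2.12 and treP at -2.11. The glycolate oxidase genes glcD (BSU28680) and glcF were higher in WN1106, by 3.31 ± 0.16 (adjusted p = 8.59e-08) and 2.49. Also higher were gsiB by 2.90 ± 0.13, yfhS by 2.35 ± 0.29, the iron uptake gene efeM by 2.28, the pheromone gene comX by 2.25, the flotillin gene floA by 2.23, yrhE by 2.22, the butyrate kinase gene buk by 2.14, oppB for oligopeptide uptake by 2.12, yqfB by 2.09 and manP for mannose uptake by 2.06.

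Of the genes fixed in advance, lctE was higher in WN1106 at 101 kPa by 1.13, katE by 1.11, sigB by 1.02, srfAA by 0.44, desE by 0.40 and resD by 0.32, and cspB was lower at -0.82 and desR at -0.39. Not past the threshold were narG at 0.18, ctc at 0.12, desK at 0.03, hmpA at -0.03, cydA at -0.04 and sspB at -0.14. By camera 5 lists were called, and 0 with an estimated correlation. In the TCA cycle list 15 of 17 genes were higher and 1 lower, with pdhA, pdhB and pdhD of pyruvate dehydrogenase at 1.89, 1.61 and 1.37. The median of the list was 0.70 (camera adjusted p = 0.0004, adjusted p = 0.691 with an estimated correlation). Oxidase and bc complex genes were lower in 16 of 20 cases and higher in 0, with ctaF at -1.76, ctaD at -1.69, ctaE at -1.68 and qcrB at -1.63. Their median was -0.53 (camera adjusted p = 0.000766, adjusted p = 0.383 with an estimated correlation).

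PBSX genes were higher in 22 of 32 cases and lower in 1, with xkdK at 0.88 and xkdO at 0.80. Over the list the median was 0.36 (camera adjusted p = 0.0004, adjusted p = 0.383 with an estimated correlation). General stress genes were higher in 39 of 83 cases and lower in 15, with yvrE at 1.56 and yjbC at 1.44 against hpf at -1.35. The list had a median of 0.18 (camera adjusted p = 0.0156, adjusted p = 0.691 with an estimated correlation). Ribosomal protein genes were higher in 27 of 49 cases and lower in 13, 28 and 14 adjusted over the list alone, with rpsC at 1.48, rplP at 1.35 and rpmC at 1.31 against rplS at -1.31. The median over the list was 0.25 (camera adjusted p = 0.0386, adjusted p = 0.691 with an estimated correlation). The other 4 called lists gave the same counts adjusted over the list alone. Flagella and chemotaxis genes went both ways, 28 of 56 higher and 19 lower, 28 and 20 adjusted over the list alone, with no call (camera adjusted p = 0.238). Median and mean differed in sign for arginine synthesis (0.07 and -0.02), biofilm matrix (0.08 and -0.03), Fur iron uptake (-0.03 and 0.20), late sporulation (-0.02 and 0.06) and pyrimidine synthesis (0.06 and -0.05), with tests that ran up and no calls.

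At 101 kPa 2683 genes passed between the strains, 1263 higher in WN1106 and 1420 lower, and 489 differed at least 2-fold, 250 higher and 239 lower. The share higher was 47.1% of those passed, against 60.03% with median centring alone, which moved genes by a median of 0.155, and of the 2-fold differences it was 51.1%, against 73.7% with median centring and 39.1% after scale normalization. Scale normalization left 684 genes passed and 46 differing at least 2-fold and ended the calls of yfhS, desE, cspB, resD, srfAA, xkdO, xkdG, xkdI and ctaD, median centring those of desR (-0.23) and cspB (-0.23), and Agilent's processed signals gave 877 of the latter. Without the 101 kPa strain array glcD stood at 2.62 and glcF at 1.90, srfAA (0.18) and resD (0.33) were no longer called, sspB turned to 0.22, desK to -0.22, and 3 lists were called, with ribosomal proteins (adjusted p = 0.0631) and general stress (adjusted p = 0.164) lost. The ribosomal call was also lost without the same-against-same array of WN624 at 101 kPa (adjusted p = 0.0578), with Agilent's processed signals (0.14), after scale normalization (0.12) and in the series matrix values (0.121), and the general stress call with median centring alone (0.108). With Agilent's processed signals narG stood at 1.05 and sspB at -0.85, both past the threshold, gsiB at 3.65, yxjJ at -3.35 and katE at 1.74. After scale normalization 37 of the 57 named genes lay nearer 0 by more than 1.5-fold, and median centring put rplS at -0.72.

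The fourth comparison asks the same of the strains at 5 kPa. The lactate permease gene lctP (BSU03060) was higher in WN1106 by 4.29 ± 0.08, or 19.5-fold (limma adjusted p = 4.53e-10), and lctE by 3.29 ± 0.06. Genes of sulfate assimilation followed, sat by 3.65 ± 0.12, sumT by 3.49, cysC by 3.33 and cysP by 3.08, and so did rocB by 3.35 and rocA by 2.96 of arginine degradation. The desaturase sensor gene desK was higher by 3.08 ± 0.08 and narG by 2.91 ± 0.09. Lower in WN1106 by the most was yhcV (BSU09230), at -3.02 ± 0.12 (adjusted p = 1.74e-08), with yxkC at -2.97, the chemoreceptor gene mcpA at -2.91, citB at -2.74, hag at -2.70 and sspB at -2.58.

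Also higher were ywsA by 3.31 and ytmA by 3.14, and lower were yhcB at -2.72, yhcA at -2.68, pftA at -2.68, yhbI at -2.66, yneN at -2.65 and ydgH at -2.58. Of the genes fixed in advance, desE was higher by 2.61, desR by 2.37, srfAA by 0.95, gsiB by 0.92, ctc by 0.62, sigB by 0.40 and hmpA by 0.37, and resD was lower at -1.07 and katE at -0.17 (adjusted p = 0.0464). Not past the threshold were cspB at 0.30 and cydA at 0.08. By camera 10 lists were called, and 0 with an estimated correlation. Flagella and chemotaxis genes were lower in 41 of 56 cases and higher in 1, with mcpA, mcpC and mcpB at -2.91, -1.91 and -1.84. The median of the list was -0.39 (camera adjusted p = 3.73e-10, adjusted p = 0.163 with an estimated correlation).

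All 3 desaturase genes were higher (median 2.61, camera adjusted p = 0.00178, adjusted p = 0.178 with an estimated correlation). Peroxide and disulfide stress genes were higher in 13 of 20 cases and lower in 2, with trxB at 2.10, mrgA at 1.70 and the catalase gene katA at 1.22. Their median was 0.62 (camera adjusted p = 0.00104, adjusted p = 0.163 with an estimated correlation). Pyrimidine synthesis genes were higher in 7 of 10 cases and lower in 0, with pyrP at 1.76 and pyrB at 1.64. Their median was 0.54 (camera adjusted p = 0.00231, adjusted p = 0.163 with an estimated correlation). Branched-chain amino acid synthesis genes were higher in 8 of 11 cases and lower in 0, with ilvK at 1.61 and ilvD at 0.91. Their median was 0.36 (camera adjusted p = 0.00231, adjusted p = 0.163 with an estimated correlation). General stress genes were higher in 43 of 83 cases and lower in 11, with ywtG at 1.03 and bmrR at 0.94. Their median was 0.20 (camera adjusted p = 0.00188, adjusted p = 0.636 with an estimated correlation).

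Fatty acid synthesis genes were lower in 10 of 15 cases and higher in 1, with fabI at -1.28, fabHA at -1.26 and accB at -1.18. Their median was -0.36 (camera adjusted p = 0.00231, adjusted p = 0.275 with an estimated correlation). Ribosomal protein genes were lower in 34 of 49 cases and higher in 1, with rplS at -0.89 and rplJ at -0.76. Their median was -0.36 (camera adjusted p = 9.56e-06, adjusted p = 0.591 with an estimated correlation). Purine synthesis genes were lower in 11 of 15 cases, with purA at -1.23, and guaB was higher by 1.22. Their median was -0.30 (camera adjusted p = 0.0107, adjusted p = 0.181 with an estimated correlation). ATP synthase genes were lower in 7 of 9 cases, with atpI at -0.92 and atpB at -0.45 (median -0.28, camera adjusted p = 0.0153, adjusted p = 0.636 with an estimated correlation). Adjusted over the list alone, the counts differed for flagella (1 higher, 43 lower), peroxide and disulfide stress (14 and 2), ribosomal proteins (1 and 36) and general stress (45 and 11). Median and mean differed in sign for proteases (-0.11 and 0.01, test down), glycolysis (-0.02 and 0.04, test up) and late sporulation (0.05 and -0.01, test up), and the test of the oxidase list ran down with a median of 0.07, all without a call.

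At 5 kPa 2288 genes passed between the strains, 1142 higher in WN1106 and 1146 lower, and 336 differed at least 2-fold, 196 higher and 140 lower. Without the 5 kPa strain array 1484 genes passed, and sigB (0.42), katE (-0.10) and atpH (-0.34) were no longer called. The katE call was also lost with Agilent's processed signals (-0.21), with median centring (-0.23) and without any of the other arrays but that of WN624 at 101 kPa in both channels, with values of -0.20 to -0.15. Scale normalization left 610 genes passed and 132 differing at least 2-fold, and ended the calls of sigB, ctc, gsiB, hmpA, atpB, atpE, atpH, purH, rplJ, rpsJ and yerD and of the lists of ATP synthase (adjusted p = 0.131) and purine synthesis (adjusted p = 0.127), while Agilent's processed signals gave 553 genes at 2-fold. Of the 68 named genes 35 lay nearer 0 by more than 1.5-fold after scale normalization. With Agilent's processed signals 8 lay as much farther, such as sspB at -3.56, ydgH at -3.24, pyrB at 2.84 and hmpA at 1.3. Also among them was pftA at -4.00, which was then lower than yhcV at -3.52. Median centring ended the purine (adjusted p = 0.0686) and general stress calls (adjusted p = 0.343), and the filter for genes above background in all channels ended the pyrimidine call (adjusted p = 0.0768). The sigB difference was not called with median centring (0.08), in the series matrix values (0.16) or in the separate-channel fit (0.19), nor was ctc with median centring (0.27).

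**Figure D2:**
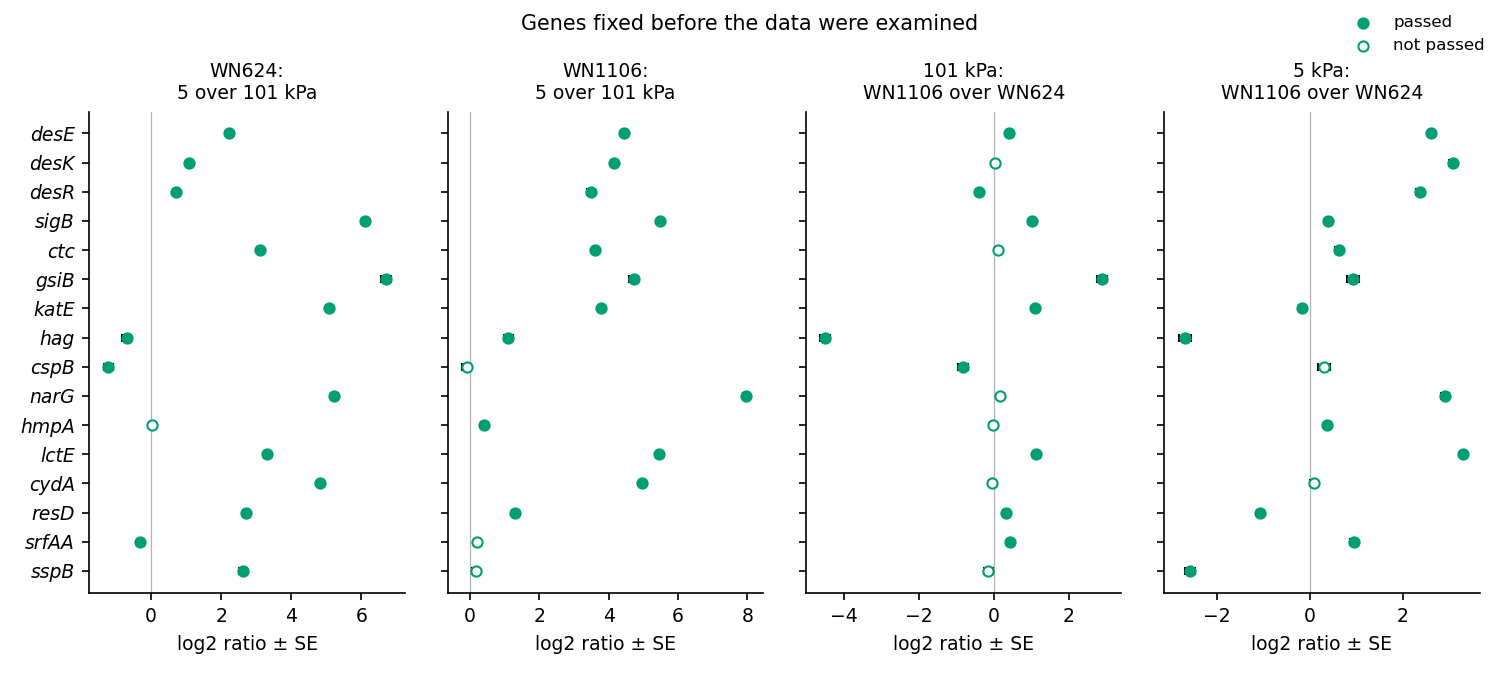
Log2 values with the standard error of the fit for the 16 genes fixed in advance, in the 4 comparisons. The pressure changes of desK are 1.09 in WN624 and 4.15 in WN1106, and hag lies at -4.50 between the strains at 101 kPa.

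The interaction tests whether the pressure change of a gene differed between the strains, as the change in WN1106 less that in WN624. It was largest for lctP, at 4.07 ± 0.08 (limma adjusted p = 3.77e-10), and for sumT at 4.01, bslA at 3.88, the arginine permease gene rocC at 3.84 and sat at 3.83. It was lowest for yhbI, at -3.49 ± 0.08 (adjusted p = 7.05e-10), citB at -3.44, yhbJ at -3.41, yneN at -3.33 and feuA at -3.14. The gene bslA fell by 1.22 in WN624 and rose by 2.66 in WN1106. Of the genes fixed in advance it was 3.05 for desK, 2.76 for desR, 2.72 for narG, 2.21 for desE, 2.15 for lctE, 1.80 for hag, 1.13 for cspB, 0.52 for srfAA, 0.49 for ctc and 0.40 for hmpA, and -2.44 for sspB, -1.97 for gsiB, -1.39 for resD, -1.28 for katE and -0.62 for sigB. For cydA it was 0.12 and did not pass (adjusted p = 0.13).

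By camera 11 lists had a pressure change that differed between the strains, and 0 with an estimated correlation. Flagella and chemotaxis genes had a lower change in WN1106 in 45 of 56 cases and a higher one in 6, with fliG at -2.19 and fliH at -2.13. Their median was -0.85 (camera adjusted p = 1.78e-08, adjusted p = 0.26 with an estimated correlation). In fatty acid synthesis it was lower for 11 of 15 and higher for 3, with accB at -2.42 (median -0.82, camera adjusted p = 0.0112, adjusted p = 0.287 with an estimated correlation). In heat shock it was lower for 12 of 16 and higher for 3, with the chaperone genes grpE at -2.04 and dnaK at -1.68. Their median was -0.67 (camera adjusted p = 0.0139, adjusted p = 0.287 with an estimated correlation). In ribosomal proteins it was lower for 32 of 49 and higher for 7, with rpsC at -1.88 (median -0.50, camera adjusted p = 7.53e-05, adjusted p = 0.466 with an estimated correlation). In PBSX it was lower for 25 of 32 and higher for 1, with xkdG at -0.98 (median -0.35, camera adjusted p = 0.000159, adjusted p = 0.26 with an estimated correlation). In purine synthesis it was lower for 11 of 15 and higher for 2, with purA at -1.27 (median -0.40, camera adjusted p = 0.027, adjusted p = 0.281 with an estimated correlation).

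The TCA cycle change was lower in WN1106 for 10 of 17 genes and higher for 3, with citB at -3.44 and citZ at -2.71. Their median was -0.31 (camera adjusted p = 0.0452, adjusted p = 0.757 with an estimated correlation). The change was higher in WN1106 for all 3 desaturase genes (median 2.76, camera adjusted p = 0.0139, adjusted p = 0.281 with an estimated correlation). Peroxide and disulfide stress genes had a higher change in 17 of 20 cases and a lower one in 3, with trxB at 2.41. Their median was 0.87 (camera adjusted p = 0.00252, adjusted p = 0.26 with an estimated correlation). Oxidase and bc complex genes had a higher change in 13 of 20 cases and a lower one in 1, with ctaD at 1.90. Their median was 0.78 (camera adjusted p = 0.00619, adjusted p = 0.281 with an estimated correlation). Pyrimidine synthesis genes had a higher change in 6 of 10 cases, with pyrP at 2.46 (median 0.44, camera adjusted p = 0.0457, adjusted p = 0.281 with an estimated correlation). Adjusted over the list alone, the counts differed for PBSX (1 higher, 27 lower), pyrimidine synthesis (5 higher, 0 lower) and ribosomal proteins (7 and 33). Median and mean differed in sign for acetoin use (0.56 and -0.11, test down), biofilm matrix (-0.02 and 0.26, test up), late sporulation (0.04 and -0.07, test up) and general stress (0.02 and -0.02, test down), all without a call.

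For the interaction 2960 genes passed, 1591 higher and 1369 lower, and 765 differed at least 2-fold, 389 higher and 376 lower. The share higher among the latter was 50.8%, against 37.4% with median centring alone. After scale normalization 20 of the 26 named genes lay nearer 0 by more than 1.5-fold. With Agilent's processed signals 6 lay as much farther, yhbI at -4.48, yhbJ at -4.09, feuA at -3.78, gsiB at -2.86, katE at -1.94 and hmpA at 1.24, and narG nearer at 1.85. The hag value was 1.14 with median centring and 1.19 in the series matrix values. Scale normalization left 884 genes passed and 123 at 2-fold and ended the calls of sigB, ctc, cspB, hmpA and srfAA, median centring those of ctc (0.01), cspB (0.16) and srfAA (0.13), and Agilent's processed signals gave 1224 at 2-fold. The purine call was lost without either pressure array (adjusted p = 0.0567), the TCA cycle call without either strain array (adjusted p = 0.169) and the pyrimidine call without the same-against-same array of WN624 at 101 kPa (adjusted p = 0.0503). The purine call ended also with median centring (adjusted p = 0.0722) and scale normalization (0.0894), the oxidase call with median centring (0.0594), the TCA cycle call with Agilent's processed signals (0.105), scale normalization (0.0897) and the stricter filter (0.0584), and the pyrimidine call with Agilent's processed signals (0.12), no background correction (0.0632) and the stricter filter (0.283).

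Across genes, the strain differences at 101 kPa and at 5 kPa had a correlation of 0.115. At least 2-fold at both pressures, 15 genes were higher in WN1106 and 32 lower, against 12.03 and 8.21 for unrelated lists of these sizes, and 19 moved in opposite directions. On average of the pressures lctP was higher in WN1106 by 2.25 ± 0.07, lctE by 2.21, pdhD by 2.08, the glutamate dehydrogenase gene rocG by 2.04 and gsiB by 1.91, and hag was lower at -3.60 ± 0.11, ylqB at -3.04, pftA at -3.01, yjfB at -2.83 and yxkC at -2.49. For this average 2466 genes passed, 1259 higher and 1207 lower, and 184 differed at least 2-fold, 92 in each direction. The share higher was 51.1% of those passed, against 64.3% with median centring, and of the 2-fold differences 50%, against 60.6% with median centring and 39.2% without the 101 kPa strain array. Scale normalization left 589 and 43 genes, and Agilent's processed signals gave 364 at 2-fold and put pftA at -3.82. All 10 genes named for this average lay nearer 0 by more than 1.5-fold after scale normalization.

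**Figure D3:**
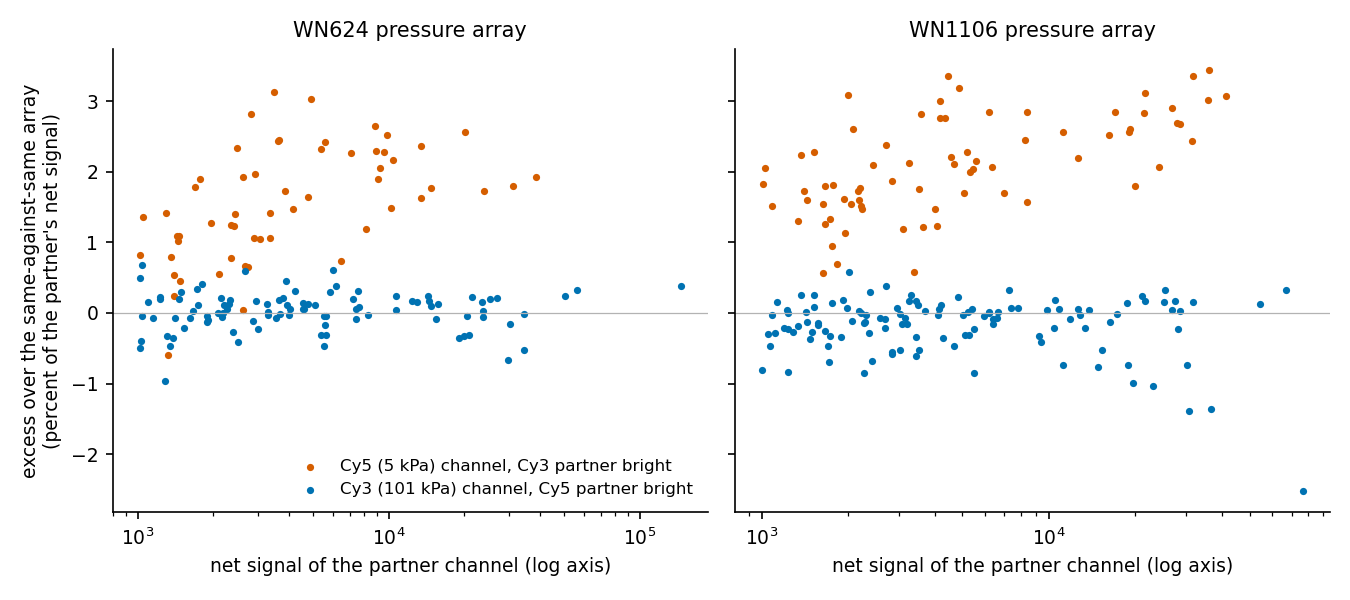
For genes whose partner channel, divided by the median ratio of the channels, was at least 12 times the signal implied by the same-against-same array, the signal in excess of the implied one is plotted as a percent of the partner's net signal, for each pressure array and direction. The median Cy5 excess was 1.63% on the WN624 array and 2.07% on the WN1106 array, and the Cy3 excess was 0.0507% and -0.0877%.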

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

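The tests of explanations in this part, all on 3 patterns, were chosen only after the results were seen, while the tests of the interaction were planned. The values below are pressure changes in WN1106 less those in WN624, log2, that passed the interaction test of limma, unless stated otherwise.

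Genes with the largest differences between the strains' pressure changes were lctP at 4.07, sumT at 4.01, bslA at 3.88, rocC at 3.84 and sat at 3.83, and yhbI at -3.49, citB at -3.44, yhbJ at -3.41, yneN at -3.33 and feuA at -3.14. Of the genes fixed in advance, desK differed by 3.05, desR by 2.76, narG by 2.72, desE by 2.21, lctE by 2.15, hag by 1.80, cspB by 1.13, srfAA by 0.52, ctc by 0.49 and hmpA by 0.40, and sspB by -2.44, gsiB by -1.97, resD by -1.39, katE by -1.28 and sigB by -0.62. The lists whose changes differed by camera, though not with an estimated correlation, had medians of 2.76 for the desaturase, 0.87 for peroxide and disulfide stress, 0.78 for the oxidases, 0.44 for pyrimidine synthesis, -0.31 for the TCA cycle, -0.35 for PBSX, -0.40 for purine synthesis, -0.50 for ribosomal proteins, -0.67 for heat shock, -0.82 for fatty acid synthesis and -0.85 for flagella and chemotaxis.

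Among control spots, which no comparison used, the brightest E1A control probe had a median net Cy5 signal of 289 over the 8 arrays, against 23.8 for the negative controls, and all 10 E1A probes exceeded the negative controls on all 8 arrays.

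Genes that fell most at 5 kPa fell less on the arrays that set the pressures side by side than the channels of other arrays imply. Another RNA preparation on those arrays stays open. Of the genes with a bright Cy3 partner 99.2% had Cy5 signal in excess. But these genes were chosen for a low implied Cy5 signal, so a preparation with a weaker fall would also give an excess. Cy3 signal counted in the Cy5 channel may be the source. The Cy5 excess had quartiles of 1.06% and 2.26% of Cy3 on the WN624 array and 1.60% and 2.68% on the WN1106 array. Carry-over of labelled RNA between the samples of an array would look alike and was not tested. The reverse excess had medians of 0.0507% and -0.0877%, but on the WN1106 array it went both ways. It was 0.331% of Cy5 for sboA and 0.166% for narI, against -1.36% for rsbW. For the first 2, which were dim in Cy3, the net Cy3 signal was 270 and 72.06, against implied signals of 48.02 and 26.31. Whether this held back their rises was not tested. For the 10 iol genes, taking off 1.82% moved their median closure only from -1.13 to -0.70, against a robust SD of 0.08 over all genes. Their own Cy5 excess on the WN1106 array had a median of 2.96% of Cy3, so a share of 1.82% could not take off all of it. No share of that size was tried. The step therefore cannot decide whether Cy3 signal in Cy5 was the whole or a part of the open loop of these genes.

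The flagellin gene hag was far lower in WN1106, at -4.50 at 101 kPa and -2.70 at 5 kPa. A sequence variant under the probes as the whole cause would give like differences at both pressures, but they differed by 1.80, by 1.14 with median centring, by 1.19 in the series matrix values and by 0.635 after scale normalization, and both hag probes were low at 101 kPa, at -4.55 and -4.41. The loess curve at bright spots would not leave the gene at -4.07 with median centring alone. Lower activity of SigD in WN1106 cannot be told apart from other sources: 24 SigD-dependent genes lay below the fla-che operon at both pressures, with a smaller gap of -1.02, but both groups were set up after the flagella list had been seen to go both ways. A variant with a partial effect on the hag signal also stays open.

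The 9 genes desE, desK, desR, narG, narH, narI, narJ, lctE and lctP rose more at 5 kPa in WN1106, by a median of 2.67 (2.76 for the 5 above background in all 16 channels), or 2.07 with Agilent's processed signals, where narG stood at 1.85, and 1.39 after scale normalization, which shrinks the ratios of comparison arrays. A wider ratio scale of the WN1106 pressure array would stretch all genes, but the slope over all genes was 1.096. Once the Cy3 share was taken off, the median was 2.68. As these genes rose in the Cy5 channel, that step could hardly move them, so it cannot decide on signal passing between channels. The reverse, Cy5 signal in Cy3, was not taken off, so whether it held back the rises of these genes was not tested. A difference between the strains at low pressure cannot be told apart from the pattern, as the array of both strains at 5 kPa, with a median of 2.96, enters the interaction itself and the genes were chosen for it. Differences between single cultures, such as the oxygen or growth stage reached, were not tested and stay open.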

How the results depend on the processing

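The treat test, the 2-fold counts, the Cy3 share and the biofilm list without epsK were chosen only after the data were seen, and the other alternatives were planned. Of the results for named genes 6699 kept direction and call under an alternative, 65 lost the call, 28 gained it and 29 reversed, and of the list medians 2704 kept the call and, if called, the direction, 40 lost the call, 20 gained it and 1 reversed. Of the counts 369 stayed within 1.5 times the main count and 42 moved farther. These tallies include alternatives that give the same estimate by construction, so they are not independent checks. For each pressure or strain comparison, leaving out any other comparison array equals using the direct arrays only. For the interaction, dropping the dye term or a same-against-same array leaves the log2 values unchanged. With the Cy3 share taken off, with no filter and with the median of probes, all 471 results compared kept their direction and call. No paired analysis was possible because each condition pair had 1 array and the labels pair no cultures. The slide as a block was not run, as all arrays shared 1 slide. Signal over background limits dim genes, whose changes the offset compresses. Agilent's processed signals have no offset but differ also in detrending and dye normalization. They gave larger pressure changes for many named genes but a smaller narG interaction, at 1.85 against 2.72, and the cause was not tested.

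Scale normalization left 1082 genes called for pressure in WN624, 1121 in WN1106, 684 between strains at 101 kPa, 610 at 5 kPa, 884 for the interaction, 1095 for the average pressure change and 589 for the average strain difference, and at 2-fold 215, 279, 46, 132, 123, 215 and 43. By its construction it gives same-against-same arrays the spread of comparison arrays, which shrinks the ratios of the latter and raises the error. Named genes that lay nearer 0 by more than 1.5-fold were counted in that order. They numbered 69 of 72, 74 of 83, 37 of 57, 35 of 68, 20 of 26, 10 of 10 and 10 of 10. None lay as much farther from 0. The treat test called 903, 1017, 210, 212, 494, 876 and 65 genes in that order, fewer because it asks for changes beyond 2-fold. Agilent's processed signals gave 877 genes at 2-fold between strains at 101 kPa, 553 at 5 kPa, 1224 for the interaction and 364 for the average strain difference, and the cause was not tested. Leaving out each array gave 1484 to 2453 genes between strains at 5 kPa and 3 to 5 lists at 101 kPa.

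With an estimated correlation camera called 0 lists in each of the 5 comparisons. The fry test called 26 lists for pressure in WN624, 24 in WN1106, 21 between strains at 101 kPa, 20 at 5 kPa and 23 for the interaction, and in either direction 29, 29, 29, 28 and 29. It is not set against other genes, so that most lists pass.

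Reversed values, for which the cause was not tested, were as follows. Median centring alone turned ATP synthase in WN1106, with atpA at -0.604, atpF at -0.591, atpH at -0.629, atpC at -0.695 and the list's median at -0.695, srfAA in WN1106 to -0.584, cspB at 5 kPa to -0.066 and narG at 101 kPa to -0.046. Scale normalization put desR at 101 kPa at 0.074, katE at 5 kPa at 0.009, hmpA in WN624 at -0.046 and at 101 kPa at 0.009, cydA at 101 kPa at 0.047, the cydA interaction at -0.027 and sspB in WN1106 at -0.22. Agilent's processed signals put hmpA at 101 kPa at 0.064 and cydA at 0.017. The series matrix values put hmpA in WN624 at -0.002, cydA at 101 kPa at 0.009 and srfAA in WN1106 at -0.132. Without the dye term desK at 101 kPa was -0.028, and the direct array put hmpA in WN624 at -0.011. Leaving out each array gave desK at 101 kPa -0.217 to 0.109, cspB in WN1106 -0.143 to 0.013, hmpA in WN624 -0.011 to 0.094, srfAA in WN1106 -0.046 to 0.289 and sspB at 101 kPa -0.262 to 0.223. Of these results desR, katE, and the ATP synthase genes and list had been called.

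Median centring moved genes by a median of -0.177 for pressure in WN1106, 0.155 between strains at 101 kPa, -0.119 for the interaction and -0.125 for the average pressure change, and the series matrix values by -0.128, -0.15 and -0.138 for pressure in WN624, in WN1106 and on average. Directions of small changes are relative to these shifts.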

Other observations

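The gene groups in this part were chosen only after their values were seen, so their tests describe these data and are no independent evidence.

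Sulfate assimilation set the strains apart at 5 kPa. All 7 genes of the cysH operon were higher in WN1106, from 1.85 for sirC to 3.65 for sat, with a median of 3.08 (camera adjusted p = 1.25e-07, adjusted p = 0.109 with an estimated correlation). Their median pressure change was 4.25 in WN1106 and 0.78 in WN624, and at 101 kPa 6 of 7 were lower in WN1106, with a median of -0.47. Arginine degradation went in opposite directions: its 6 genes all fell at 5 kPa in WN624, with rocA at -2.22 and a median of -1.10, and all rose in WN1106, with rocB at 2.78 and a median of 1.19. Between the strains at 5 kPa all 6 were higher in WN1106 (median 2.78, camera adjusted p = 4.04e-06, adjusted p = 0.109 with an estimated correlation). The 10 inositol genes fell in both strains, with medians of -2.33 in WN624 and -4.73 in WN1106 (camera adjusted p = 0.00372 and 0.000385, adjusted p = 0.437 and 0.521 with an estimated correlation).

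The flagellar genes parted into groups between the strains. At 101 kPa 25 of 29 genes of the fla-che operon were higher in WN1106, with fliG at 1.91 and a median of 0.99 (camera adjusted p = 1.19e-09, adjusted p = 0.311 with an estimated correlation), while 23 of 31 SigD-dependent genes were lower, with hag at -4.50, pgdS at -2.08 and a median of -0.89 (camera adjusted p = 3.17e-07, adjusted p = 0.283 with an estimated correlation). At 5 kPa 30 of the 31 SigD-dependent genes were lower, with a median of -1.40 (camera adjusted p = 3.68e-17, adjusted p = 0.0711 with an estimated correlation), and 16 of the 29 operon genes, with a median of -0.26 (camera adjusted p = 0.000292, adjusted p = 0.371 with an estimated correlation).

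The Cy5 excess differed between gene groups on the WN1106 pressure array: its median was 2.96% of Cy3 for the 10 iol genes and 1.86% for 63 other genes. On the strain array at 101 kPa 2 genes, hag and ylqB, met the brightness criterion, with a median of 3.07%.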
